A study of Mus musculus with 11 samples.

How the data were processed

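RNA was taken from sorted kidney cells with the Qiagen RNeasy micro kit and made into libraries with the Kapa stranded mRNA-Seq kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17, TopHat2, Partek and the mouse build mm10, without saying how reads were counted, so whether strand was used is not given in the sources used here. Genes that overlap or share near-identical copies are therefore uncertain. The deposited values come in 2 tables, one holding the E16.5 Six2+ and Six2- libraries and one the E16.5 Cited1+ and P2 Six2+ libraries, each with 24454 rows in the same order.

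The authors call the deposited values TPM, but they scale as RPKM. TPM sums to 1000000 in every library, while these summed to 321882.9 to 433447.3, with a coefficient of variation of 9.0%. Sums weighted by transcript length, from GENCODE release M21 for 96.1% of genes, varied by 1.6%. In genes with a single annotated transcript, low values multiplied by length fell on whole-read steps, with 49.9% to 59.9% of them within 0.05 of a whole multiple where chance gives 10%. The steps imply 16500000 to 43800000 reads per library, with P2 Six2+ replicate 2 the lowest and Six2- replicate 2 the highest. The design written before the data were examined assumed TPM, and the same test was kept, since neither unit is a count. RPKM shares a ceiling across genes, so a few abundant transcripts can lower all others; the 50 highest genes took 14.5% to 22.2% of the sums, and ribosomal protein genes took 22.3% in Six2+ replicate 2 and 12.0% to 18.0% in the others. A total of 27 rows per table carried a date in place of a gene symbol and were left out, holding 0.125% to 0.215% of the values. The 24427 genes left had no repeated symbols and no mitochondrial transcripts.

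The deposited tables also hold the authors' fold and p-value columns. Recomputing them showed that in the table of Six2+ and Six2- cells 100.0% of the deposited fold ratios equal the ratio of group means with 0.01 added to each, and 100.0% of the deposited p-values equal an unequal-variance test of all libraries, within a relative tolerance of 1e-06. In the table of Cited1+ and P2 Six2+ cells 100.0% of the deposited ratios and p-values instead compare the Cited1+ libraries with the first P2 library alone. The 4 columns of group means that the authors deposited were not used. The authors' short lists hold genes with a ratio above 3 or below 0.33, a p-value below 0.05 and a mean above 5 in the higher group. Redone with both P2 libraries, the same filter gave 135 higher genes, 119 of them on the deposited list of 137, and 159 lower genes, 156 of them on the deposited list of 227.

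Groups were taken from the labels. Each comparison within a table was fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend, over genes with a mean of at least 1 in the libraries of the fit. Benjamini-Hochberg adjustment was over all genes tested, with a threshold of 0.05. The contrasts across tables were to be tested only if all libraries summed to the same total; they did not, so levels are given side by side. A total of 25 gene lists of cell types and processes, fixed before the data were examined from general knowledge of the kidney, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 3 genes tested. With an estimated correlation no list passed in either comparison. Members were counted by the test over all genes. Counts adjusted over the list alone stand beside them where they differ. Counts of 4 or fewer members moved by 1 or 2 in several lists when single libraries were left out.

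The genes named were set by a rule fixed beforehand: Six2, Cited1, Foxd1, Wnt4 and Pax8 always; the 8 largest rises and 8 largest falls among genes that passed, whose groups did not overlap and whose mean was at least 5 in the higher group, skipping gene models and sex-linked genes; and from each list the 2 passing members with the largest change, with up to 2 more where the set passed. Of these the text gives most, and some are not reported here. Rpl14-ps1, Mrgpra6, Umod, Krt18, Egr1, Xist, Ddx3y, Prkce and the Hox and claudin genes were named after their values were seen. Coordinates are from the RefSeq annotation of GRCm38, the build called mm10.

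The fit was tested on simulated data with 100 genes changed at each size. Simulated genes varied independently, and those changed were not among the lowest. The rates below therefore need not hold for real libraries, whose genes can vary together. In the simulated Six2+ comparison 69% of log2 changes of 1 and 98% of changes of 2 were recovered, with 10 false calls among 11882 genes; in the simulated Cited1+ comparison the shares were 58% and 90%, with 6 false calls among 11876 genes. Libraries of the same number were checked for pairing from their deviations from group means. In the Six2+ and Six2- groups, correlations of same-numbered libraries were 0.47, 0.455 and 0.404, and the highest with another number was 0.149. Deviations within a group cancel out, which ties these correlations together, so pairing by number is possible but not shown. The labels do not say what a number shares. Alternatives were another pseudocount (0.1), no filter or a mean of at least 5, median-of-ratios and quantile scaling, leaving out haemoglobin and ribosomal protein genes, no trend, a replicate block, leaving out each library in turn, and for gene lists an estimated correlation and fry. Rescaling to a common total and a term for sex were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.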

Results

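Messenger RNA was sequenced from cells sorted by flow cytometry from developing kidneys of CFW mice, an outbred strain. The 11 libraries fell into 4 groups. Embryonic kidneys at E16.5 carrying the Six2TGC reporter were sorted into Six2+ cells (n = 3) and the Six2- remainder (n = 3). Cited1+ cells (n = 3) came from E16.5 kidneys carrying a Cited1tagRFP reporter, and a second set of Six2+ cells (n = 2) came from Six2TGC kidneys at postnatal day 2 (P2). Six2 marks the nephron progenitors of the cap mesenchyme, and Cited1 marks the least committed of them. Values are on the RPKM scale, in which reads are divided by transcript length and by library depth. The low values imply 16500000 to 43800000 reads per library. Fold changes are differences of log2(value + 1), which understate the change of low genes, and are given with their SE. Group levels are means ± SD. The labels do not say whether libraries of a group came from separate animals, so adjusted p-values measure the spread between these libraries, which may be technical. In the second comparison libraries of one group differed in sex-linked transcripts and so cannot all share the same animals.

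The first comparison asked which transcripts set E16.5 Six2+ cells apart from all other sorted kidney cells of the same stage. Six2, the gene behind the sort, stood at 340 ± 21.8 in Six2+ and 7.53 ± 8.18 in Six2- libraries, and the spread in the latter came from replicate 3 at 16.98. Crym, a thyroid hormone binding protein, rose by a log2 fold change of 5.24 (SE 0.24; 287 ± 77.9 against 6.61 ± 2.05). Eya1, a transcriptional partner of Six2, rose by 4.58 (SE 0.25), the homeobox gene Uncx by 4.18 (SE 0.27), and Cited1 by 4.07 (SE 0.47; 43.7 ± 13.7 against 2.13 ± 2.49). Six3, the neighbour of Six2 on chromosome 17, rose by 4.61 (SE 0.17; 44.9 ± 7.03 against 0.884 ± 0.32). In the opposite direction, the fibrillar collagen gene Col3a1 stood at 4.08 ± 2.37 in Six2+ and 828 ± 193 in Six2- libraries, a log2 fold change of -7.43 (SE 0.33). All of these had limma adjusted p-values of at most 0.000166. The difference in Six2 follows from the sort and is not a finding.

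Other genes with large differences were Nell1 (log2 fold change 4.41, SE 0.12), the proteoglycan gene Spock2 (4.38, SE 0.29) and the cartilage collagen gene Col2a1 (4.24, SE 0.50) on the Six2+ side. On the Six2- side stood the opioid precursor Penk (-6.52, SE 0.26) and the haemoglobin genes Hba-a1 (-6.54, SE 0.81), Hba-a2 (-6.69, SE 0.83), Hbb-bs (-6.59, SE 0.81), Hbb-b1 (-6.57, SE 0.82) and Hbb-bt (-6.33, SE 0.72). Haemoglobin genes are near-identical copies, so the level of each single copy is uncertain. Wnt4, which drives the transition of progenitors to epithelium, was higher in Six2+ cells (63.0 ± 2.80 against 11.7 ± 2.79; log2 fold change 2.36, SE 0.17), as was Pax8 (53.9 ± 2.09 against 13.6 ± 1.65; 1.92, SE 0.12). Foxd1, a marker of stromal progenitors, was lower (36.5 ± 7.97 against 79.5 ± 21.9; -1.09, SE 0.22, adjusted p = 0.00416).

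In GRCm38, the assembly also called mm10, Six2 lies on chromosome 17 from 85662736 to 85688254 and Six3 from 85613608 to 85626191. Cited1 lies on chromosome X from 102247378 to 102252181, Wnt4 on chromosome 4 from 137277635 to 137299501, and Col3a1 on chromosome 1 from 45311538 to 45349706. All 5 are annotated as protein-coding, and the files give 1 value per gene and library.

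Marker lists of kidney cell types separated the sorts. Counts adjusted over the list alone are given where they differ. Of 28 nephron progenitor genes tested, 21 were higher and 1 was lower in Six2+ cells, or 22 and 2 adjusted over the list alone (camera adjusted p = 1.58e-08; adjusted p = 0.192 with an estimated correlation). The 21 include Six2, the gene behind the sort, and the set was not retested without it. Of 28 interstitial stroma genes, 27 were lower in Six2+ cells, among them Pdgfra (-6.27, SE 0.21) and Col1a2 (-6.05, SE 0.20), with adjusted p = 4.18e-22, and adjusted p = 0.171 with an estimated correlation. Of 18 macrophage and leukocyte genes, 17 were lower, led by Lyz2 (0.188 ± 0.102 against 29.6 ± 2.98), with adjusted p = 1.18e-13, and adjusted p = 0.348 with an estimated correlation. Of 15 endothelial genes, 14 were lower and 1 was higher, with Eng at -3.57 (SE 0.21) and Cdh5 at -3.01 (SE 0.17). The set passed with adjusted p = 1.58e-08, and adjusted p = 0.358 with an estimated correlation. Of 10 erythroid genes, 8 were lower, or 9 adjusted over the list alone (adjusted p = 2.14e-05; adjusted p = 0.484 with an estimated correlation). Of the 10, 8 are haemoglobin genes, and Hbb-bt and Hbb-b2 had identical values here too, so the count and set test overstate the number of separate measurements. Haemoglobin genes took 0.4%, 2.07% and 3.81% of the summed values in Six2- replicates 1, 2 and 3 against 0.01% to 0.02% in Six2+ libraries.

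The epithelial lists differed. Of 22 proximal tubule genes 13 fell below the filter on low values, and the 9 tested were all lower in Six2+ cells (15 lower and 0 higher of 22 with no filter), including Hnf4a (0.0614 ± 0.0441 against 3.79 ± 0.644), with adjusted p = 4.15e-06, and adjusted p = 0.348 with an estimated correlation. Of 15 podocyte genes, 8 were lower and 1 was higher, with Podxl at -3.76 (SE 0.44). As a set it had adjusted p = 0.00332, and adjusted p = 0.777 with an estimated correlation. The 25 early nephron differentiation genes went both ways, 7 higher and 12 lower, or 8 and 13 adjusted over the list alone (adjusted p = 0.12), with the cadherin gene Cdh4 at 2.74 (SE 0.18) and Mecom at -2.45 (SE 0.14). The 10 ureteric bud and collecting duct genes did so too, 3 higher and 6 lower (adjusted p = 0.112). Gfra1, a receptor subunit for Gdnf, was at 3.88 (SE 0.28) and Gata2 at -2.77 (SE 0.21). Of 4 loop of Henle and distal tubule genes tested, 2 were higher and 2 lower (adjusted p = 0.975), with Ppp1r1a at 3.10 (SE 0.23) and Sostdc1 at -1.65 (SE 0.32). That list's median (0.04) and mean (0.38) lay above 0 and its test pointed down. Among 9 neural and glial genes, 2 were higher and 2 lower (adjusted p = 0.374), with Stmn2 at -2.92 (SE 0.53) and Elavl4 at 1.63 (SE 0.22).

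Among the process lists, extracellular matrix genes were lower in Six2+ cells, 17 of 23 against 2 higher, led by Col6a2 (-5.92, SE 0.18) and Col6a1 (-5.57, SE 0.17), with adjusted p = 1.82e-10, and adjusted p = 0.348 with an estimated correlation. Of 18 imprinted growth genes, 11 were lower and 2 higher, led by Plagl1 (-4.82, SE 0.14) and Dlk1 (-4.37, SE 0.15), and 13 were lower adjusted over the list alone. The list's adjusted p was 0.000136, and adjusted p = 0.171 with an estimated correlation. Interferon and antigen presentation genes were lower in 5 of 9 cases, or 6 adjusted over the list alone, with Ifitm3 at -4.92 (SE 0.23), adjusted p = 0.00222, and adjusted p = 0.358 with an estimated correlation. Of 20 immediate early and dissociation stress genes, 7 were lower, or 6 adjusted over the list alone, including Atf3 (-2.67, SE 0.54), with adjusted p = 0.00348, and adjusted p = 0.777 with an estimated correlation. That call ended without Six2+ replicate 1 (adjusted p = 0.0558) or Six2- replicate 3 (0.0655), the other single-library tests giving 1.69e-05 to 0.00664, and 14 genes were lower without Six2+ replicate 3. The remaining lists did not pass as sets. Higher and lower members numbered 4 and 3 of 30 cell cycle genes (adjusted p = 0.374; 2 and 1 adjusted over the list alone), 3 and 3 of 10 cell cycle inhibitors (0.772), 5 and 1 of 12 fetal growth genes (0.36) and 4 and 3 of 20 glycolysis genes (0.473). The higher glycolysis genes numbered 1 without Six2- replicate 1 or 2 and 7 without Six2- replicate 3. They numbered 6 and 6 of 13 Wnt beta-catenin targets (0.513), 7 and 6 of 18 FGF and receptor tyrosine kinase response genes (0.532; 8 and 6 adjusted over the list alone), 4 and 5 of 13 Notch pathway genes (0.543; 4 and 6) and 4 and 5 of 18 TGF-beta and BMP response genes (0.543; 4 and 6). The median of the last list was 0.05 and its mean -0.30. The lower Notch genes numbered 2 without Six2- replicate 2. None of 5 sex-linked genes passed (0.715). Single members of these that passed included Cdkn1a (2.08, SE 0.15), Peg10 (-4.10, SE 0.17), Slc2a3 (-2.80, SE 0.16), the Wnt antagonist gene Dkk1 (-3.93, SE 0.13), Shisa2 (3.44, SE 0.16), Hes6 (1.70, SE 0.15) and Bmp7 (3.03, SE 0.15), and of the cell cycle list Mcm7 (0.63, SE 0.13) and Ccne1 (-0.66, SE 0.12). Oxidative phosphorylation genes missed the threshold (adjusted p = 0.0601) and passed it with the replicate number as a block (adjusted p = 0.0375; adjusted p = 0.806 with an estimated correlation and no block), with 3 of 30 members higher without the block, or 1 adjusted over the list alone. Without single libraries its adjusted p ranged from 0.00205 (without Six2+ replicate 3, 6 members higher) to 0.377 (without Six2+ replicate 2), and 1 member was higher without Six2- replicate 1.

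In all, 2440 genes were higher and 2149 lower in Six2+ cells among 11882 tested with limma at an adjusted p below 0.05, or 603 and 1229 with an absolute log2 fold change of at least 1. Higher genes made up 53.2% of calls, and 39.2% after each library was rescaled to the same total (1744 higher, 2700 lower). Without Six2- replicate 2 the higher genes numbered 1618. The authors' deposited table lists 246 genes as higher and 545 as lower, and of the 245 and 544 tested here every one was called in the same direction.

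**Figure D1:**
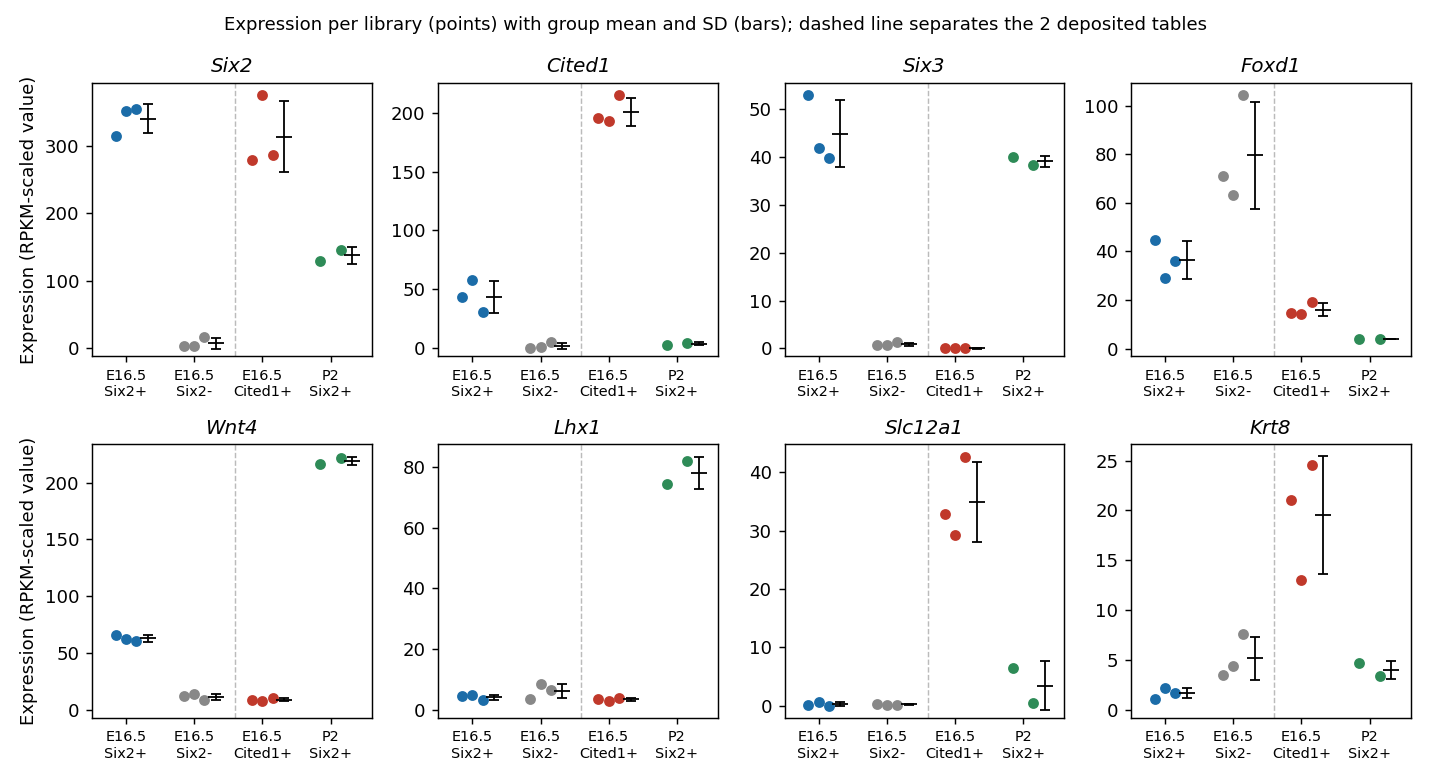
Expression on the RPKM scale (vertical axes, linear) of 8 genes in each of the 11 libraries (points), with the group mean and SD as bars; the dashed line separates the libraries of the 2 deposited tables. Six3 is at 44.9 ± 7.03 in E16.5 Six2+ and 39.2 ± 1.14 in P2 Six2+ libraries and at most 0.18 in the Cited1+ libraries, while Slc12a1 is highest in the Cited1+ libraries.

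The second comparison set E16.5 Cited1+ cells against P2 Six2+ cells, sorted by progenitor markers in the embryo and shortly after birth. Whether either gate held only progenitors was not tested, so differences need not lie within progenitors. Stage, sorting marker and reporter line all differed between these groups. Cited1, the gene behind one of the sorts and so not a finding, stood at 201 ± 11.9 in Cited1+ and 3.76 ± 1.31 in P2 Six2+ libraries. Six2 was also higher in Cited1+ cells (313 ± 52.9 against 137 ± 12.3; log2 fold change 1.17, SE 0.16, limma adjusted p = 0.00203). Genes of commitment to the nephron were higher at P2: Wnt4 stood at 9.01 ± 1.32 in Cited1+ and 219 ± 3.81 in P2 libraries (-4.47, SE 0.13), Lhx1, a regulator of nephron patterning, at 3.52 ± 0.403 and 78.0 ± 5.36 (-4.13, SE 0.12), and Pax8 at 31.4 ± 5.48 and 289 ± 13.9 (-3.17, SE 0.15). The glycolytic enzyme gene Aldoa was higher in Cited1+ cells, at 191 ± 15.3 against 63.9 ± 1.51 (1.56, SE 0.11).

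Further genes with large differences on the Cited1+ side were the homeobox gene Meox2 (4.09, SE 0.26), the Polycomb-associated gene Phf19 (3.99, SE 0.11), Traf1 (3.96, SE 0.25), Crym (125 ± 42.8 against 10.5 ± 8.16), the axon guidance receptor gene Robo2 (3.40, SE 0.15) and Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb (3.42, SE 0.58). Slc12a1 stood at 6.4 and 0.48 in the 2 P2 libraries, and its adjusted p rose from 0.00547 to 0.05 with no filter on low values, which ended the call. Ocm stood at 10.8 ± 1.13 in Cited1+ libraries and was listed at 0 in both P2 libraries. On the P2 side were neuropeptide Y, Npy (-5.75, SE 0.19), Six3 (0.0615 ± 0.107 against 39.2 ± 1.14; -5.25, SE 0.14), the myelin protein gene Pmp22 (-4.68, SE 0.13), Bmp2 (-3.85, SE 0.16), the laminin gene Lama4 (-3.78, SE 0.13) and Sdk2 (-3.78, SE 0.12). Foxd1 was higher in Cited1+ cells (16.1 ± 2.68 against 3.99 ± 0.138; 1.76, SE 0.15).

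Of 28 nephron progenitor genes, 15 were higher and 7 lower in Cited1+ cells, or 17 and 7 adjusted over the list alone (camera adjusted p = 0.00174; adjusted p = 0.265 with an estimated correlation), and the lower ones numbered 3 without either P2 library. The 15 higher progenitor genes include Cited1 and Six2, the genes behind the sorts, and the set was not retested without them. Early nephron differentiation genes were lower in Cited1+ cells in 21 of 28 cases and higher in 3, including Lef1 (-3.39, SE 0.17), with adjusted p = 4.47e-13, and adjusted p = 0.179 with an estimated correlation. Of 14 Wnt beta-catenin targets, 9 were lower and 1 higher, with the Wnt deacylase gene Notum at -3.58 (SE 0.15) and Ccnd1 at 45.6 ± 4.24 against 304 ± 16.8, and 11 were lower adjusted over the list alone. The set passed with adjusted p = 3.23e-07, and adjusted p = 0.265 with an estimated correlation. Of 12 Notch pathway genes, 8 were lower and 2 higher, with the ligand gene Jag1 at -2.87 (SE 0.12), the targets Hey2 at -2.58 (SE 0.17) and Hey1 at -2.40 (SE 0.12), and Hes6 at 1.63 (SE 0.17), and 9 were lower adjusted over the list alone. As a set it had adjusted p = 3.56e-05, and adjusted p = 0.327 with an estimated correlation. The Notch and Wnt lists share members with the early nephron differentiation list, among them Jag1, Hey1, Lef1 and Ccnd1. Their results are therefore not separate evidence. Of 17 TGF-beta and BMP response genes, 9 were lower and 3 higher, with Id4 at -2.40 (SE 0.12) and Bmp4 at -2.22 (SE 0.11), and 11 were lower adjusted over the list alone. The list's adjusted p was 0.000329, and adjusted p = 0.265 with an estimated correlation. The higher members numbered 1 without Cited1+ replicate 1 or P2 replicate 2. Extracellular matrix genes were lower in 11 of 23 cases and higher in 3, or in 1 without Cited1+ replicate 1 or P2 replicate 1, with Lamc1 at -1.70 (SE 0.10) and Nid2 at -1.90 (SE 0.12). The set passed with adjusted p = 0.000551, and adjusted p = 0.366 with an estimated correlation.

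Markers of other cell types differed between these sorts and moved apart. Ureteric bud and collecting duct genes were higher in Cited1+ cells in 17 of 20 cases, or 18 adjusted over the list alone, including Tfcp2l1 (2.45, SE 0.19), Cdh1 (13.4 ± 1.12 against 2.74 ± 0.964) and Krt8 (19.5 ± 5.88 against 4.08 ± 0.899), with adjusted p = 1.2e-07, and adjusted p = 0.265 with an estimated correlation. Of 15 loop of Henle and distal tubule genes, 8 were higher and 1 lower, with Mal at 1.75 (SE 0.20) and Cldn19 at 1.54 (SE 0.20), and 9 were higher adjusted over the list alone. As a set it had adjusted p = 0.00717, and adjusted p = 0.539 with an estimated correlation. The higher ones numbered 5 without Cited1+ replicate 1, Cited1+ replicate 3 or P2 replicate 2. All 7 erythroid genes tested were higher in Cited1+ cells (adjusted p = 0.000551; adjusted p = 0.366 with an estimated correlation), at low levels such as 32.4 ± 12.6 against 6.43 ± 3.16 for Hbb-bs. Of the 7, 6 are haemoglobin genes, and Hbb-bt and Hbb-b2 had identical values in every library, so the count and set test overstate the number of separate measurements. Of 15 podocyte genes, 9 were lower and 1 higher, with Sema3g at -2.73 (SE 0.21), and 2 were higher adjusted over the list alone. The list's adjusted p was 0.000329, and adjusted p = 0.265 with an estimated correlation. Of 10 macrophage and leukocyte genes, 9 were lower, among them C1qa (0.445 ± 0.299 against 4.11 ± 0.604), with adjusted p = 2.61e-05, and adjusted p = 0.22 with an estimated correlation. Lists that did not pass as sets were proximal tubule (6 higher and 1 lower of 13; adjusted p = 0.0737), interstitial stroma (12 and 8 of 25, or 12 and 11 adjusted over the list alone; 0.877), endothelium (1 and 0 of 7, or 4 and 0; 0.0949) and neural and glial genes (1 and 1 of 3; 0.894). The proximal tubule list passed with median-of-ratios scaling (adjusted p = 0.0481) and without P2 replicate 1 (0.00105), and its adjusted p ranged up to 0.593 over all alternatives. The neural list had a median of 0.06 and a mean of -0.25. The higher proximal tubule genes numbered 3 without Cited1+ replicate 1, Cited1+ replicate 3 or P2 replicate 2, the lower stroma genes 5 without P2 replicate 1 and the higher endothelial genes 3 without Cited1+ replicate 2. Within these lists Lrp2 stood at 1.39 (SE 0.16), Aldh1a2 at -2.15 (SE 0.11), Col1a1 at 2.12 (SE 0.13), Ramp2 at 1.23 (SE 0.11) and Fabp7 at -1.65 (SE 0.24).

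Glycolysis genes were higher in Cited1+ cells in 16 of 20 cases, and in 10 without Cited1+ replicate 1. They were led by the lactate transporter gene Slc16a3 (1.92, SE 0.18), Aldoa, the lactate dehydrogenase gene Ldha (218 ± 45.8 against 74.7 ± 4.14) and Tpi1 (1.41, SE 0.11), with adjusted p = 3.23e-07, and adjusted p = 0.265 with an estimated correlation. Gapdh did not pass (1142 ± 127 against 1110 ± 61.9). Oxidative phosphorylation genes passed as a set (adjusted p = 0.00155; adjusted p = 0.593 with an estimated correlation), but the 7 of 30 members that were higher (4 adjusted over the list alone) rested on single libraries, being 0 without either P2 library, 1 without Cited1+ replicate 1, 3 without Cited1+ replicate 3 and 23 without Cited1+ replicate 2. Of 12 genes of the fetal growth program, 5 were higher and 1 lower, with the RNA-binding protein genes Igf2bp3 (14.9 ± 1.02 against 1.49 ± 0.338) and Igf2bp1 (19.2 ± 2.20 against 6.87 ± 0.179) among the former and Mycn (-1.40, SE 0.32) the latter. Its adjusted p was 0.0314, with adjusted p = 0.265 with an estimated correlation, and the call ended without Cited1+ replicate 2 (adjusted p = 0.116), against 0.0125 to 0.0394 without each other library. Mycn lost its call without P2 replicate 2 (log2 change -0.82, adjusted p = 0.055). Interferon and antigen presentation genes were lower in 3 of 9 cases, led by B2m (-1.60, SE 0.26), with adjusted p = 0.0298, and adjusted p = 0.265 with an estimated correlation. Adjusted over the list alone, 1 was higher and 4 lower. The call ended without Cited1+ replicate 2 (adjusted p = 0.0529) or P2 replicate 2 (0.0936), against 0.013 to 0.0232 without each other library. Imprinted growth genes did not pass as a set (7 higher and 2 lower of 15; adjusted p = 0.0737), with Mest higher in Cited1+ cells (1094 ± 44.9 against 318 ± 2.41) and the long noncoding RNA H19 lower (857 ± 179 against 3373 ± 69.4). Nor did cell cycle genes (2 higher and 5 lower of 30, or 0 and 0 adjusted over the list alone; adjusted p = 0.0933), cell cycle inhibitors (4 and 3 of 10; 0.997), FGF and receptor tyrosine kinase response (7 and 4 of 18, or 8 and 5; 0.603), immediate early and dissociation stress (7 and 3 of 20; 0.22) and sex-linked genes (0 and 0 of 5; 0.997). The sex-linked list had a median of 0.57 and a mean of 0.21, and its test pointed down. The lower cell cycle genes numbered 0 without Cited1+ replicate 1 or P2 replicate 1 and 10 without Cited1+ replicate 2. The higher inhibitors numbered 1 and the higher immediate early genes 3 without P2 replicate 1. The lower FGF response genes numbered 2 without P2 replicate 2. Members that passed were Cdkn1a (-1.15, SE 0.20), Spry1 (-1.66, SE 0.18), Shisa3 (1.61, SE 0.13) and Junb (1.59, SE 0.21). Cdc20 (0.60, SE 0.18) and Cenpa (0.53, SE 0.15) of the cell cycle list passed, and both lost their calls without Cited1+ replicate 1, Cited1+ replicate 3 or either P2 library (adjusted p from 0.0672 to 0.226).

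In all, 1930 genes were higher and 1512 lower in Cited1+ cells among 11876 tested with limma at an adjusted p below 0.05, or 461 and 512 with an absolute log2 fold change of at least 1. Higher genes made up 56.1% of calls, and 45.8% after rescaling to the same total (1619 higher, 1917 lower). The higher and lower counts were 791 and 875 without Cited1+ replicate 1, 3012 and 2145 without Cited1+ replicate 2, 1042 and 1078 without Cited1+ replicate 3, 936 and 841 without P2 replicate 1, and 873 and 788 without P2 replicate 2. Cited1+ replicate 3 also had 20737 genes above 0, against 15009 to 17496 in the other libraries. The authors' deposited table lists 137 genes as higher and 227 as lower, of which 134 of 137 and 223 of 225 tested here were called in the same direction; its fold changes and p-values use 1 of the 2 P2 libraries.

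**Figure D2:**
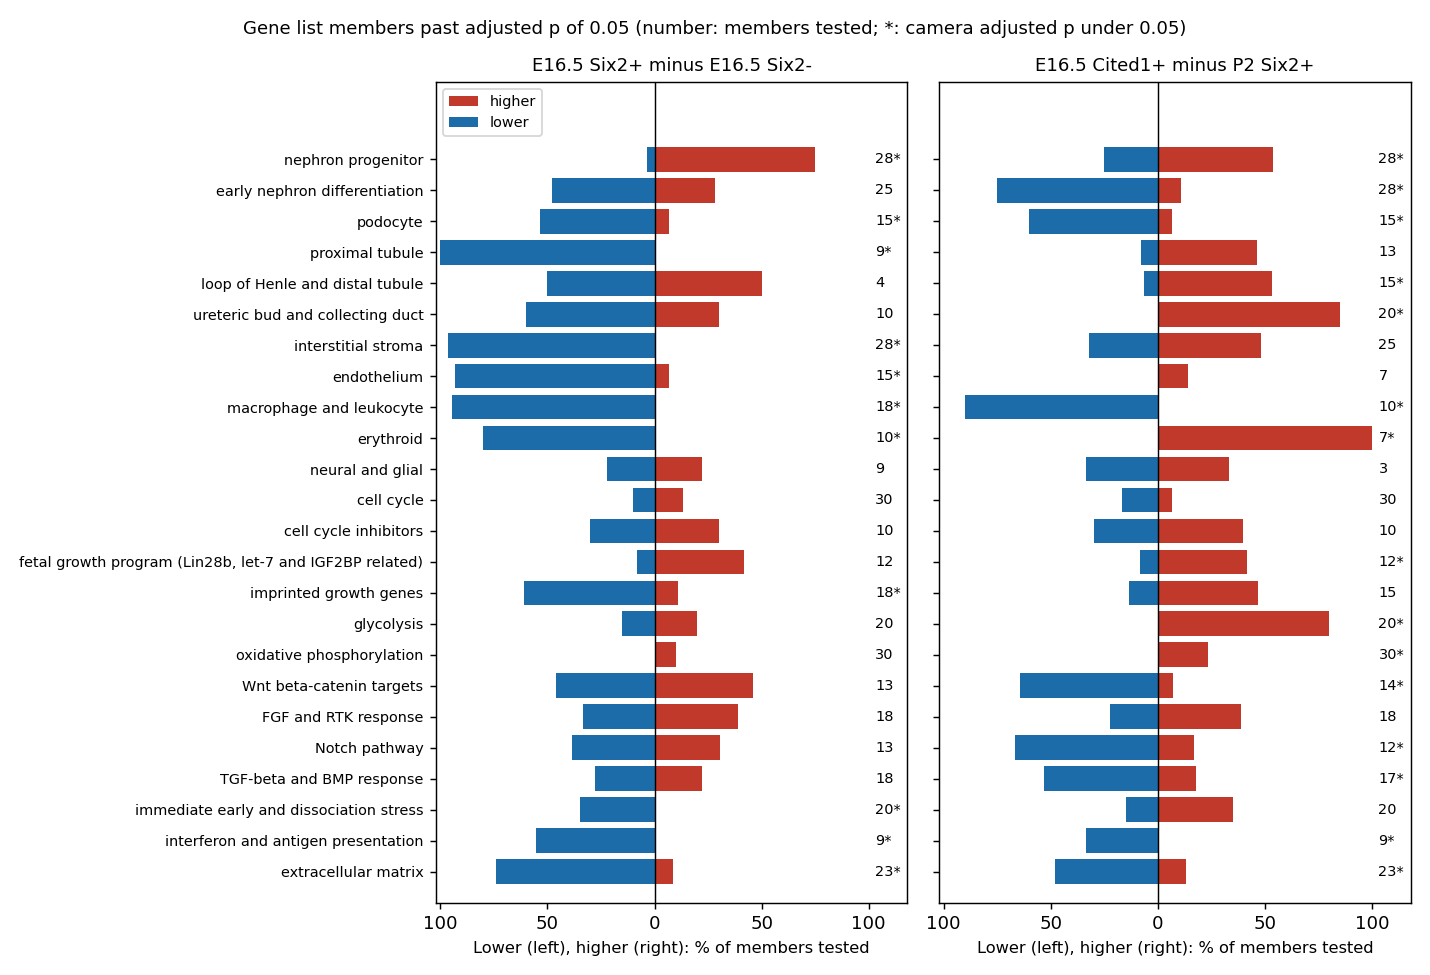
Percent of the tested members of 24 gene lists that were lower (blue, left) or higher (red, right) at a limma adjusted p below 0.05 in each comparison; numbers are members tested and asterisks mark a camera adjusted p below 0.05 with the preset correlation. Stroma, endothelium and macrophage lists lie on the Six2- side of the first comparison, and in the second early nephron differentiation lies on the P2 side and glycolysis on the Cited1+ side. None of the marked lists passed with an estimated correlation.

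The 2 remaining contrasts, E16.5 Six2+ against P2 Six2+ cells and E16.5 Cited1+ against E16.5 Six2+ cells, cross the 2 deposited tables and are given as levels with no test. Library sums differed, and 6 genes, among them Rpl14-ps1 and Mrgpra6, were below 0.1 in all 6 libraries of one table and above 2 in all 5 of the other, so a difference between tables cannot be told apart from one between groups. Igf2bp3 stood at 12.6 ± 2.83 in E16.5 Six2+, 14.9 ± 1.02 in E16.5 Cited1+ and 1.49 ± 0.338 in P2 Six2+ libraries, and Aldoa at 174 ± 35.0, 191 ± 15.3 and 63.9 ± 1.51. Lhx1 stood at 4.34 ± 0.822, 3.52 ± 0.403 and 78.0 ± 5.36, and Wnt4 at 63.0 ± 2.80, 9.01 ± 1.32 and 219 ± 3.81. Cited1 itself stood at 43.7 ± 13.7, 201 ± 11.9 and 3.76 ± 1.31, and Meox2 at 4.97 ± 0.746, 25.0 ± 4.12 and 0.582 ± 0.666. Slc12a1 stood at 0.314 ± 0.377, 34.9 ± 6.91 and 3.44 ± 4.18 in the same order, and at 0.229 ± 0.142 in E16.5 Six2- libraries.

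The libraries also differed in sex-linked transcripts. All 6 libraries of the first comparison held both Xist (23.12 to 61.57) and the Y-linked Ddx3y (7.17 to 13.78). In the second comparison Cited1+ replicate 2 and P2 replicate 2 held Xist (140.22 and 158.03) with Ddx3y at 0 and 0.12, while the other 3 held Ddx3y (18.4 to 23.08) with Xist at most 0.14. With sex as a term in the model, chosen after seeing the data, 1802 genes were higher and 1420 lower in Cited1+ cells.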

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

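Rescaling to a common total, the term for sex and set tests without single libraries were chosen after seeing the data. Of 79 named genes called between Six2+ and Six2- cells, 78 kept their call in every alternative that tested them. The exception was Ndufv1 without Six2- replicate 1. Of 85 between Cited1+ and P2 cells, 74 did, and none of either set reversed. Genes that an alternative left out, such as haemoglobin genes or those with a mean below 5, could not lose their call there. With no filter 10 of the 85 lost their call, among them Slc12a1 at an adjusted p of 0.05. The count of Six2+ lower genes was 1230 with a mean of at least 5, where 8717 genes were tested. It was 1229 with an absolute log2 fold change of at least 1, where the higher count was 603; that setting adds a minimum change to the same calls. Without single libraries the Six2+ counts ranged from 1618 to 2382 higher and 1673 to 2206 lower, the lowest without Six2- replicate 2. The Cited1+ higher count was 1139 with no filter; the cause was not tested. At an absolute log2 fold change of at least 1 the Cited1+ counts were 461 higher and 512 lower. Without single libraries they ranged from 791 (without Cited1+ replicate 1) to 3012 (without Cited1+ replicate 2) higher and from 788 (without P2 replicate 2) to 2145 lower; where 1 P2 library was left, it was assumed to vary like the Cited1+ libraries. The higher count was also 936 and 873 without P2 replicates 1 and 2, and 1042 without Cited1+ replicate 3. With the replicate block it was 895 higher and 868 lower, and the endothelium (adjusted p = 0.0278), imprinted growth (0.0278) and proximal tubule (0.0356) lists passed (0.366, 0.425 and 0.593 with an estimated correlation and no block), with 1 Hoxa and 6 Hoxc genes lower and 1 ribosomal protein gene higher; same-numbered libraries there correlated at 0.042 and -0.028 over 2 pairs. With 2 P2 libraries the correlations with same and other numbers are opposites by construction and cannot show pairing, so no pairing was assumed. Replicates 1 of both groups held Ddx3y and replicates 2 of both held Xist, so the block is in part a term for sex. Cited1+ replicate 3 has no P2 library of its number, so the block takes it out of the group contrast. In the Six2+ comparison the block gave 3603 higher and 2632 lower and changed no call of a named gene or list other than oxidative phosphorylation. With an estimated correlation 0 of the 11 lists that passed between Six2+ and Six2- cells and 0 of the 15 between Cited1+ and P2 cells kept their call. The fry test, which has a different hypothesis, lost 2 and 2. Between Six2+ and Six2- cells these were podocyte (fry adjusted p = 0.0694) and immediate early and dissociation stress (0.23). Between Cited1+ and P2 cells they were loop of Henle and distal tubule (0.0944) and oxidative phosphorylation (0.12). Between Six2+ and Six2- cells fry added ureteric bud (adjusted p = 0.0468), Wnt target (0.0468) and FGF response (0.0103) lists. Between Cited1+ and P2 cells fry added stroma (0.00299), endothelium (0.0296), imprinted growth (0.00986) and FGF response (0.00483) lists. Keeping rows with repeated symbols apart was not run, as no symbol repeats, and neither were the fits joining both tables, whose condition was not met. Implied depths ran from 16500000 to 43800000 reads, and their effect on the calls was not tested.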

Other observations

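Hox genes, which set position along the body axis, were tested as a family only after their values were seen. Of 31 tested, 23 were higher and 0 lower in E16.5 Six2+ than in Six2- cells, or 1 lower after median-of-ratios, quantile or total rescaling (camera p = 1.21e-07; p = 0.155 with an estimated correlation, and 0.0393 with the replicate block), led by Hoxd12 (20.7 ± 2.22 against 0.846 ± 0.221) and Hoxb9 (33.5 ± 7.40 against 5.29 ± 1.72). All 8 Hoxb and all 7 Hoxc genes tested were higher there under each scaling tried. Between Cited1+ and P2 Six2+ cells, all 7 Hoxc genes were lower in Cited1+ cells under each scaling, with a median log2 change of -0.95 (p = 9.32e-06; p = 0.0761 with an estimated correlation) and Hoxc4 at -1.43 (SE 0.16), and 3 of 8 Hoxb genes were higher (p = 0.00252; p = 0.0648 with an estimated correlation), with Hoxb6 at 1.02 (SE 0.13). Of 9 Hoxa genes 5 were lower and 0 higher, or 6 lower after median-of-ratios scaling and 6 of 10 after total rescaling, and of 7 Hoxd genes 4 were higher and 1 lower, or 3 and 2 after median-of-ratios or total rescaling. The difference between clusters was not tested. Hox genes lie close together with antisense transcripts, so reads of neighbours cannot be fully told apart.

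Claudins, the tight junction proteins, were also chosen after seeing the data. Of 14 tested, 9 were higher and 2 lower in Cited1+ than in P2 Six2+ cells under each scaling tried (camera p = 0.0142; p = 0.255 with an estimated correlation). Cldn4 (2.66, SE 0.36), Cldn7 (2.08, SE 0.27) and Cldn8 (1.92, SE 0.15) were higher, and Cldn5 (-2.68, SE 0.15) and Cldn11 (-1.97, SE 0.15) were lower. Ribosomal protein genes were higher in 33 of 81 cases and lower in 0 in Cited1+ cells, with 21 higher after quantile scaling. Egr1 stood at 747 ± 64.5 in Cited1+ and 344 ± 43.4 in P2 libraries.

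The tests of explanations in the next 3 paragraphs were chosen after the patterns were seen, though the gene lists and most scalings they use were planned. Those of a single Cited1+ library, transcript length and library scaling had their expected outcomes written before their values were computed, but after the gene fits with those scalings had been run. The others had them written after. Six3 was high in both groups of Six2+ cells from Six2TGC kidneys and near 0 in Cited1+ cells. The mean of 44.9 in E16.5 Six2+ libraries is part of that pattern and leaves no room for Six3 RNA that begins only after birth in Six2TGC kidneys. It cannot date expression of the native gene, since a transgene source, taken up below, stays open. Six3 RNA that accompanies Six2 in any progenitor is argued against by the Cited1+ libraries, where Six2 stood at 313 and Six3 reached at most 0.064% of it, against 26.3% and 31.1% in the P2 libraries. A candidate explanation is that Six3, which lies 36.5 kb from Six2 in GRCm38, is carried or driven by the Six2TGC transgene; this stays open, because reporter line and sorting marker changed together, and no group held Cited1+ cells of that line. Within 500 kb of Six2, Srbd1 and Camkmt did not pass between Cited1+ and P2 cells (log2 changes of -0.08 and -0.02), and Prkce was higher in Cited1+ cells (0.68).

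Of 20 ureteric bud and 15 loop and distal tubule markers, 17 and 8 were higher in Cited1+ than in P2 Six2+ cells, while the proximal tubule list did not pass (adjusted p = 0.0737). The loop and distal tubule list lost its call with fry (adjusted p = 0.0944). A single Cited1+ library as the cause is argued against, since the median difference of 35 markers to the P2 mean was at least 0.98 in each of the 3. With 17 and 8 markers already called from the same libraries, that outcome was likely beforehand. It does not cover the P2 mean, which rests on 2 libraries. A general loss of progenitors that raises every other cell type alike is argued against too, since the lists moved apart: the podocyte list had a median log2 change of -0.74 and the macrophage list -1.25, against 1.99 for erythroid, 0.68 for endothelial, 0.66 for proximal tubule and 0.58 for stroma genes. Tubule and ureteric bud cells within the Cited1+ gate stay open as a hypothesis, since the share of the 35 markers with a positive change, 97.1%, restates the pattern and cannot decide, and 1 of the 35 is on another list and 9 had a mean of at least 1 in E16.5 Six2+ libraries. Slc12a1, whose call ended with no filter (adjusted p = 0.05), stood at 34.9 ± 6.91, Krt18 at 21.1 ± 6.22 and Krt8 at 19.5 ± 5.88 in Cited1+ libraries, and Umod at 1.55, 2.65 and 7.21 against 6.16 and 0.48 in the P2 libraries, while reporter expression in such cells and stage were not tested.

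Of 20 glycolysis genes 16 were higher in Cited1+ than in P2 Six2+ cells, or 10 without Cited1+ replicate 1 (adjusted p = 3.23e-07; adjusted p = 0.265 with an estimated correlation). Transcript length is argued against as the whole cause. The list median of 0.76 lay above all 10000 random lists matched on length and level, at percentile 100. Those lists had a median of 0.05, and the highest reached 0.47. Their genes were drawn independently, while glycolysis genes can vary together, so the percentile overstates the certainty. Ribosomal protein genes, with a median of 0.56, also lay above 0.47, so passing it is not particular to glycolysis. The lowest list median over 4 scaling alternatives was 0.71. Size factors in this comparison ran only from 0.971 to 1.043, so scaling by them could hardly move the median. Quantile scaling, among the 4, lowered the median of ribosomal protein genes from 0.56 to 0.25, so its outcome was not fixed. Only a scaling difference that quantile scaling removes is argued against. A difference of stage stays open as a hypothesis, since marker and reporter line changed with it in this comparison. E16.5 Six2+ libraries share marker and reporter line with P2, and Slc12a1 stood there at 0.314 and Krt8 at 1.71. Summed means of the 20 glycolysis genes tested in each comparison were 3333.6 in E16.5 Six2+, 3191.1 in Cited1+ and 2112.5 in P2 libraries. These untested levels go against tubule cells, marker or reporter line as the whole cause. They cross the deposited tables, so a difference between tables stays possible.

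The real grouping of the 6 E16.5 Six2+ and Six2- libraries gave 4589 genes and the highest of the other splits gave 0. Only 10 splits exist, of which 1, the real one, gave as many, so their number is too small for a share under 0.05.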
